A study of Mus musculus
Rattus norvegicus with 6 samples.

How the data were processed

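The series holds 6 RNA-seq libraries of myelinated co-cultures, in which Schwann cells from sciatic nerves of 2-day-old Sprague Dawley rats were grown with dorsal root ganglion neurons of mouse embryos (embryonic day 14.5). Per the labels, cultures received ascorbic acid at 50 ug/ml for 14 days, which starts myelination, and then AT-56 or its vehicle DMSO for 7 more days. AT-56 is an inhibitor of lipocalin-type prostaglandin D2 synthase, the enzyme encoded by Ptgds. Each group had 3 libraries. Poly(A) libraries were made from 2500 ng of total RNA and sequenced for 150 cycles in single-end mode, with 42000000 fragments per sample on average, per the labels' protocols.

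The authors used Trimmomatic, kallisto and DESeq2, per the submitters' processing notes, with the genome builds mm10 (mouse) and rn5 (rat). Their versions, and how reads were divided between the species, are not given in the sources used here. The 2 deposited tables, for rat and for mouse genes, hold the authors' comparison of the groups and no values of single libraries. Per the file headers, the columns are those of a DESeq2 result table. For each gene the authors gave a mean of normalized counts over all libraries (a signal that is never negative), a log2 fold change with its standard error, a Wald statistic (a score equal to the log2 fold change divided by its standard error), a p-value and an adjusted p-value. No source used here says which group is the numerator of the fold change. All signs are therefore given as deposited, and a negative value cannot be read as lower or higher with AT-56. The sign has the same meaning for all genes of a table, and whether it has the same meaning in both tables is not stated either.

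The mouse table as deposited had lost the decimal point of numbers of 1 or more. This affected 24806 means, 1906 log2 fold changes and 7000 Wald statistics, which had been written with up to 10 decimals. The point of log2 fold changes and Wald statistics was put back after the first digit. The restored log2 fold change divided by its standard error then differed from the restored statistic by at most 4.3e-10 over 39458 genes. The p-value computed from the statistic differed from the deposited p-value by at most 8.9e-11. For 3 genes the statistic was taken from the p-value, and 7 p-values above 1 as printed were recomputed from the statistic. When rat values were written in the same way and restored, 100.0% of statistics and 90.4% of means were recovered. The other means came out 10 times too low or more, because trailing zeros had been dropped, so mouse means are approximate. Gene names were taken from the name column, since the mouse protein columns matched names only in part.

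The tests fixed before the data were examined assumed counts per library. The planned edgeR quasi-likelihood test was not run because the authors deposited no such values, and the authors' adjusted p-values replaced that test, at a threshold of 0.05, and only genes with an adjusted p-value were called tested. The standard errors fell towards 0 at the lowest means, as they do when fold changes are moderated towards 0. In the rat table their median was 0.027 at means up to 1 and 0.157 at means from 10 to 100. Folds of weakly expressed genes therefore understate differences. Some abundant rat genes also had large errors, such as Acta2 (mean 8305, SE 0.162), against a median of 0.095 at means from 1000 to 10000. Their folds may be understated as well, so rankings by fold and the 1.5-fold count rest on unevenly moderated values. In the mouse table the median standard error was 0.405 at means up to 1 and 0.541 at means from 10 to 100, so fold sizes of the 2 tables are not on the same scale. The titles number 2 libraries of each group as biological replicates and give the other 1 no number. Whether all 3 came from separate animals and cultures is not given in the sources used here, and if they did not, the p-values measure technical spread. Library totals were not analysed here. The deposited standard error is the only measure of spread given for each value. At a low mean a small standard error reflects this moderation and does not show high precision.

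From the deposited values, 27 gene lists fixed before the data were examined were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the Wald statistics, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a table. Where a symbol stood on several rows, the row with the highest mean was used. Members were also counted after adjustment over the list alone. An estimated correlation and fry need values per library and were not computed. Differences between the tables were computed per shared symbol as the difference of the log2 fold changes divided by the root of the summed squared standard errors, two-sided, with Benjamini-Hochberg adjustment. This treats the tables as independent although both came from the same libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

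Genes named in the text followed a rule fixed before the data were examined. Ptgds, Ptgdr and Ptgdr2 came first. The 10 largest differences in each direction followed, among genes past 0.05 with an ordinary symbol and a mean of at least 5 CPM (relative to the table's summed means). Where fewer than 5 passed in a direction, the 5 with the smallest p were given as values, and then up to 4 members with the smallest p in each list discussed. The rule's conditions on single libraries could not be applied. Other genes were named after their values were seen, and the text says so.

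The procedures were tested on simulated data with the real standard errors, with 200 genes changed. For single genes the simulated change was divided by its standard error and independent normal noise was added. The simulated changes were not moderated towards 0, so the recovered shares can be too high, most of all for weakly expressed genes. The share of false calls holds for such independent noise only. In the rat table with 20943 genes, 59.0% of genes with a log2 change of 0.5 and 100.0% of those with a change of 1.0 were recovered, and 4.8% of calls were false. In the mouse table with 12472 genes, 9.0% of genes with a change of 1.0 and 70.0% of those with a change of 2.0 were recovered. For the difference between the tables, with 9221 symbols, 12.0% of differences of 1.0 and 94.0% of differences of 2.5 were recovered. Of 3 lists shifted by 1 SD, 2 were recovered, and of 21 lists that were not shifted, 0 were called. The simulated statistics were independent between genes, so these counts do not show how the list test behaves when genes are correlated. Alternatives comprised no filter on low means, a minimum mean of 5 CPM, a fold of at least 1.5, leaving out genes at a near equal level in both tables, ranks, a preset correlation of 0.05, leaving out each list's largest member, centring on the median, and turning the rat sign in differences between the tables. Mouse positions are those of the RefSeq annotation of GRCm38.p6, which is mm10. No rat annotation was used here.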

Results

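Gene expression was compared between myelinated co-cultures of rat Schwann cells and mouse dorsal root ganglion neurons treated with AT-56 and those given DMSO, with 3 libraries per group. The series title places the comparison in the context of Schwann cell metabolism. Because the cells came from different species, the authors deposited 1 table of rat genes and 1 of mouse genes. The mean normalized counts summed to 36902523 in the rat table and to 1368312 in the mouse table, so that rat genes held 96.42% of the total. The mouse sum is a lower bound, because some restored mouse means came out too low, and the rat share can therefore be too high. Totals of single libraries were not analysed here. The titles number 2 libraries per group as biological replicates and leave the other 1 without a number, so the independence of all 3 is unclear. The rat table listed 39537 genes, 20943 of them with an adjusted p-value, and the mouse table listed 48543 genes, 12472 of them with an adjusted p-value.

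Schwann cell transcripts were found mainly in the rat table, while neuronal genes were divided between the tables. The myelin gene Mpz had a mean normalized count of 254100 in the authors' deposited table for rat and of 2458 in that for mouse, which was 0.967% of the rat value. Plp1, another myelin gene, had means of 57330 and 718 in the authors' deposited tables, and the glial transcription factor Sox10 had means of 17030 and 461. The neuropeptide gene Calca had means of 27.2 for rat and 4023 for mouse in the authors' deposited tables, and the axonal growth gene Stmn2 had means of 15.9 and 2077. Of the 29 pan-neuronal genes with a value in both tables, 16 had the higher mean in the mouse table, as did 11 of 23 sensory neuron genes, 1 of 16 genes of Schwann cell and glial identity and 0 of 26 myelin genes. The median mouse level was 257% of the rat level for the pan-neuronal and 44.2% for the sensory neuron genes. It was 1.14% for the glial identity genes and 1.26% for 34 extracellular matrix genes. Mouse means are approximate because their decimal points had been lost.

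**Figure D1:**
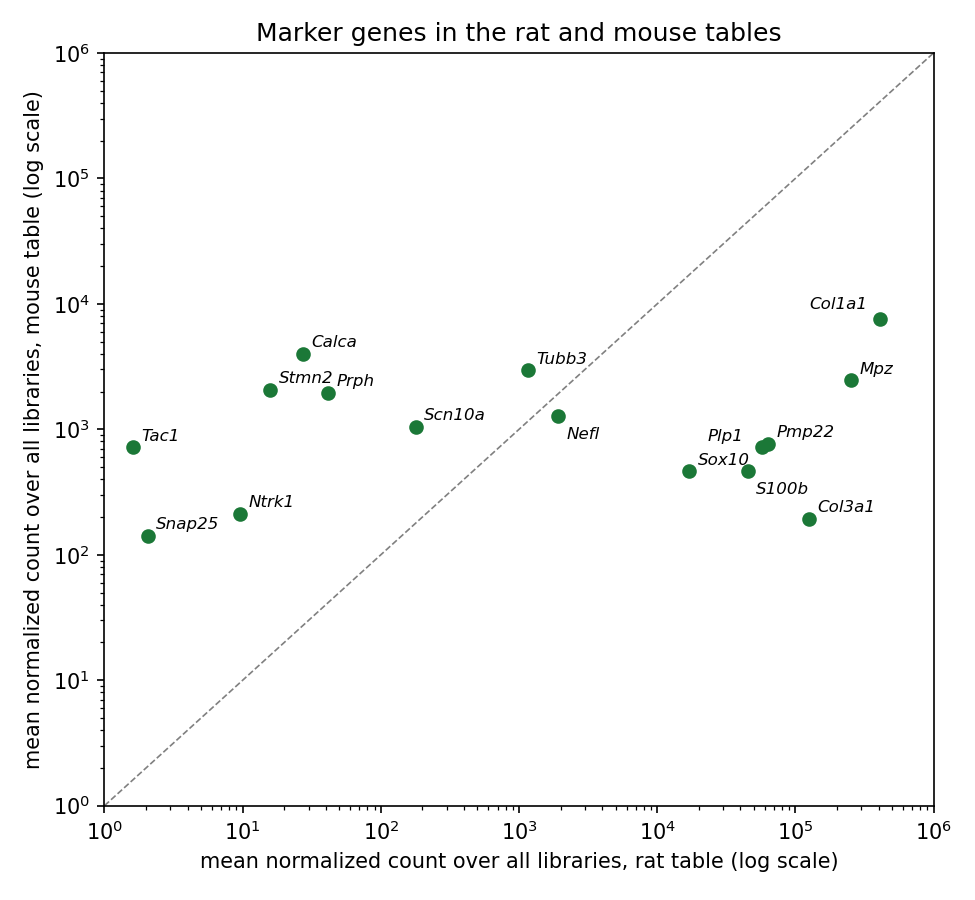
Mean normalized counts over all libraries of 16 marker genes in the rat table (horizontal, log scale) and the mouse table (vertical, log scale), with the line of equal levels dashed. Schwann cell and matrix genes such as Mpz lie below the line, and the neuronal genes lie above it except Nefl, which lies below.

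Ptgds, which encodes the enzyme inhibited by AT-56, was weakly expressed in the rat table. Its log2 fold change in the authors' deposited table was -0.55 (SE 0.152, adjusted p = 0.0291), at a mean normalized count of 39.9. The prostaglandin D2 receptor gene Ptgdr2 had a log2 fold change of -0.07 (SE 0.149) in the authors' deposited table for rat, and the other receptor gene, Ptgdr, had a mean of 0.144 and no adjusted p-value. In the authors' deposited table for mouse, Ptgds (chromosome 2, 25466709 to 25470110 in mm10) had a mean of 1.28 and no adjusted p-value. Which group is the numerator of these fold changes is not given in the sources used here. Signs are therefore reported as deposited, and genes of equal sign moved in the same direction within a table.

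An adjusted p of 0.05 was passed by 258 rat genes in the authors' deposited table, 138 with a negative and 120 with a positive sign. Among the negative genes, Prkca, which encodes protein kinase C alpha, had the largest difference of those named, with a log2 fold change of -1.91 in the authors' deposited table (SE 0.0843, adjusted p = 5.36e-109), a 3.75-fold difference. Hmgcs2, the mitochondrial enzyme that controls ketone body synthesis, followed at -1.85 (SE 0.133, adjusted p = 5.56e-40) in the authors' deposited table. The cholesterol exporters Abcg1 and Abca1 had log2 fold changes of -1.54 (SE 0.145) and -1.23 (SE 0.111) in the authors' deposited table. Srebf1, a transcription factor of lipid synthesis, and Scd, a stearoyl-CoA desaturase, were at -1.26 (SE 0.126) and -1.17 (SE 0.123) there, per the authors' deposited table. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was at -1.14 (SE 0.146) and the acyl-CoA synthetase gene Acsl3 at -1.05 (SE 0.107) in the authors' deposited table. Col11a2 and Tbc1d30 completed the 10 named under the naming rule, at -1.01 (SE 0.153) and -0.96 (SE 0.138) in the authors' deposited table. Adjusted p-values of these 10 genes were at most 2.69e-08 in the authors' deposited table.

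Among called genes with an ordinary symbol and at least 5 CPM, the 10 largest positive differences lay between 0.74 and 1.19 in the authors' deposited table. Hspb7, a small heat shock protein gene, had a log2 fold change of 1.19 (SE 0.164, adjusted p = 5.89e-10) and the chloride channel gene Clcnkb one of 1.09 (SE 0.163, adjusted p = 2.6e-08) in the authors' deposited table. These 2 genes are on consecutive rows and may share reads, as may Prkca and the tRNA gene Trnaa-agc on the row after it, which had a log2 fold change of -1.86 in the authors' deposited table. Ppp2r2b, a regulatory subunit of protein phosphatase 2A, was at 0.89 (SE 0.127) in the authors' deposited table. The matrix genes Smoc1 and Frem1 were at 0.88 (SE 0.137) and 0.84 (SE 0.144) in the authors' deposited table, and Gpnmb, which encodes a membrane glycoprotein, at 0.77 (SE 0.14). Fibin, the proteoglycan gene Cspg4 and Tm4sf1 lay between 0.75 and 0.76 in the authors' deposited table. The abundant collagen gene Col3a1 was at 0.74 (SE 0.124, adjusted p = 1.56e-06) in the authors' deposited table. Required to differ by at least 1.5-fold, 128 of the 258 genes remained, 60 negative and 68 positive.

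**Figure D2:**
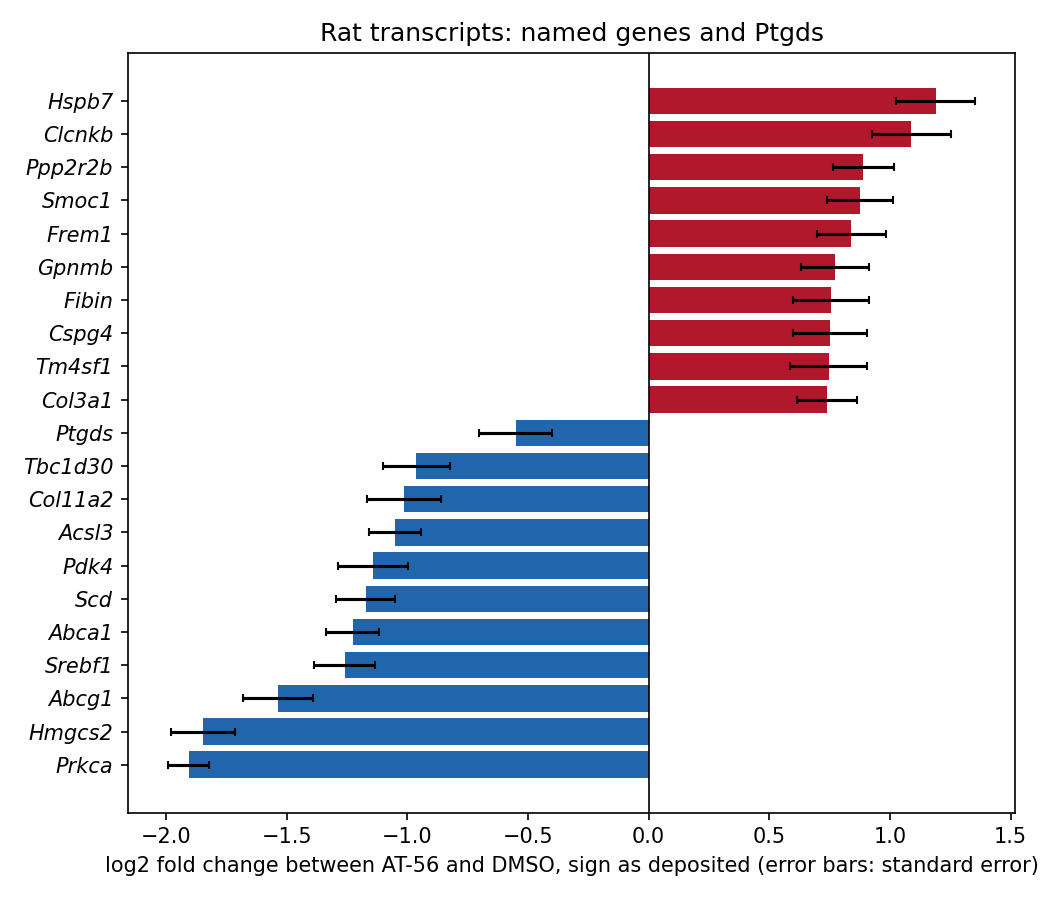
Log2 fold changes between AT-56 and DMSO, sign as deposited (horizontal axis), of Ptgds and the 20 named rat genes, with standard errors as error bars, from the authors' deposited table. Negative values reach -1.91 for Prkca and positive values 1.19 for Hspb7.

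Among 27 gene lists, the strongest difference in the rat table was in fatty acid and myelin lipid synthesis. Of its 31 tested members, 7 passed the threshold over all genes, 7 of them negative, and 9 passed when adjusted over the list alone, 9 of them negative. Besides Srebf1, Acsl3 and Scd these were the acetyl-CoA carboxylase gene Acaca at -0.62 (SE 0.0879), Scd2 at -0.66 (SE 0.109), the desaturase gene Fads2 at -0.32 (SE 0.073) and the elongase gene Elovl1 at -0.41 (SE 0.107) in the authors' deposited table. Scd2 had a mean normalized count of 202720 in the authors' deposited table, and reads of Scd, Scd2 and Scd4, which are close relatives on consecutive rows, could be divided between them. The list's statistics were lower than those of other genes (limma cameraPR, adjusted p = 4.45e-17). A test on ranks, which sets aside the size of the differences, gave an adjusted p of 0.0528. Of the 31 members 20 were negative, with a median log2 fold change of -0.19. Whether the call rested on the 7 called members alone was not tested.

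Fatty acid oxidation and ketone bodies showed the same direction. Of 32 tested members 4 passed over all genes and 5 when adjusted over the list alone, each with a negative sign. In the authors' deposited table they were Hmgcs2, the lipase inhibitor gene Angptl4 at -1.70 (SE 0.164), Cpt1a, which encodes the carnitine transferase that admits fatty acids to mitochondria, at -0.85 (SE 0.0889), and the mitochondrial carrier gene Ucp2 at -0.76 (SE 0.134). Angptl4 acts on lipid uptake and Ucp2 is not an enzyme of fatty acid oxidation, and 28 members did not pass. The list test gave an adjusted p of 8.08e-11 (limma cameraPR), and 0.106 on ranks.

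The glycolysis and lactate list did not pass, with 18 of 26 tested members negative and a median log2 fold change of -0.04 (limma cameraPR, adjusted p = 0.0612). It passed without the filter on low means (adjusted p = 0.0115). A single member, the enolase gene Eno2, passed over all genes, at -0.32 (SE 0.0855, adjusted p = 0.0235) in the authors' deposited table. Pfkl and Aldoa were at -0.24 (SE 0.0981) and -0.18 (SE 0.0813) in the authors' deposited table and did not pass. In pyruvate entry and the TCA cycle Pdk4 passed, with 27 members that did not (list adjusted p = 0.823). Nuclear oxidative phosphorylation had 1 member past the threshold of 49, Atp5a1 at 0.23 (SE 0.0678, adjusted p = 0.0464) in the authors' deposited table (list adjusted p = 0.268), and the 13 genes of mitochondrial DNA had none (list adjusted p = 0.415). Cholesterol synthesis had none of 26 either, with 10 members negative and 16 positive (limma cameraPR, adjusted p = 0.503). Its member with the smallest p, Hmgcs1, was at 0.29 (SE 0.0964, adjusted p = 0.135) in the authors' deposited table.

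Myelin genes of the rat table were on balance positive. Of 26 tested members 20 had a positive sign, with a median log2 fold change of 0.11, 2 passed over all genes and 3 when adjusted over the list alone. The first 2 were Ncmap, a gene of non-compact myelin, at 0.71 (SE 0.159, adjusted p = 0.00175) and the connexin gene Gjb1 at 0.53 (SE 0.145, adjusted p = 0.0254) in the authors' deposited table. The myelin glycoprotein gene Mag was at 0.42 (SE 0.132, adjusted p = 0.0973) in the authors' deposited table. The list test gave an adjusted p of 0.00454 (limma cameraPR), which became 0.0758 with a preset correlation of 0.05. Among genes of repair and immature Schwann cells, Gfap passed over all genes at -0.54 (SE 0.141, adjusted p = 0.0171) in the authors' deposited table, and 4 of 27 members passed when adjusted over the list alone, 4 of them negative (list adjusted p = 0.21).

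Markers of other cell types were examined in the same table. Endothelial and mural markers were positive, with 10 of 11 tested members above 0 and a median log2 fold change of 0.30 (limma cameraPR, adjusted p = 4.13e-05). The smooth muscle actin gene Acta2 at 0.62 (SE 0.162, adjusted p = 0.0181) and the VEGF receptor gene Flt1 at 0.60 (SE 0.163, adjusted p = 0.0262) passed in the authors' deposited table. Fibroblast and perineurial markers had Col3a1 past the threshold and a list adjusted p of 0.0649, which was 0.0177 without the filter on low means. The lists of Schwann cell and glial identity, satellite glia and macrophages had adjusted p-values of 0.177, 0.536 and 0.349, and the pan-neuronal and sensory neuron lists had 0.962 and 0.415. The identity list had 1 of 16 members past the threshold, Sostdc1, at 0.58 (SE 0.101, adjusted p = 5.19e-06) in the authors' deposited table. The satellite glia list had Apoe at -0.64 (SE 0.154, adjusted p = 0.00515) in the authors' deposited table. The neuronal injury list (adjusted p = 0.349) had the neuropeptide gene Npy at 0.62 (SE 0.162, adjusted p = 0.0177) in the authors' deposited table, next to an unnamed locus of the same mean that could share its reads. Of the prostaglandin list, Slco2a1, which encodes a prostaglandin transporter, was at 0.58 (SE 0.146, adjusted p = 0.0107) in the authors' deposited table beside Ptgds (list adjusted p = 0.169). Hypoxia response genes included the paralogous transcription factors Epas1 at -0.62 (SE 0.0871) and Hif1a at -0.27 (SE 0.074) in the authors' deposited table, while the list as a whole did not pass (adjusted p = 0.349). In all, 4 of 27 lists passed in the rat table, and the adjusted p of the other 23 lay between 0.0612 and 0.962.

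Of 12472 tested mouse genes, 0 passed an adjusted p of 0.05 in the authors' deposited table, where DESeq2 is the tool per the submitters' processing notes, and 739 (5.93%) had an unadjusted p under 0.05. The standard errors there were about 0.5 on the log2 scale. In simulated data 9.0% of genes with a log2 change of 1.0 and 70.0% of those with 2.0 were recovered. Differences of 4-fold or more could therefore still be missed. The smallest adjusted p was 0.0558 in the authors' deposited table and was shared by several genes. They included Itgav (chromosome 2, 83722303 to 83806917 in mm10), an integrin subunit gene, at -1.69 (SE 0.387), and Zpld1 at -2.10 (SE 0.493) in the authors' deposited table. With a positive sign, the matrix gene Postn (chromosome 3, 54359267 to 54391041) was at 2.25 (SE 0.498), the immediate early gene Nr4a1 at 2.46 (SE 0.583), Egfl8 at 2.35 (SE 0.56) and Sorcs1 at 2.12 (SE 0.509) in the authors' deposited table. Cdh19, a glial cadherin gene, was at 2.06 (SE 0.511, adjusted p = 0.076) in the authors' deposited table. Itgb3, Utp14b and Spp1 were at -1.62 (SE 0.43), -2.01 (SE 0.544) and -1.58 (SE 0.447) in the authors' deposited table, with adjusted p-values of 0.138 or more. Utp14b stood on the row after Acsl3, which was at -0.98 (SE 0.469) in the authors' deposited table, and may share its reads.

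Gene lists of the mouse table differed although single genes did not pass. The median log2 fold change of the tested mouse genes was 0.12, and 61.5% of all tested mouse symbols were positive. The list test compares members with other genes. Some lists share members, such as Postn (matrix and glial identity) and Cdh19 (glial identity and satellite glia), so their calls are not independent. Extracellular matrix genes were positive in 26 of 27 tested members, with a median of 0.94 (limma cameraPR, adjusted p = 7.1e-12). Genes of Schwann cell and glial identity were positive in 13 of 15, with a median of 0.98 (limma cameraPR, adjusted p = 4.09e-08). Adjusted over the list alone, 3 matrix members and 4 glial members passed, each with a positive sign. Besides Postn and Cdh19 the glial members with the smallest p were Lgi4 at 1.45 (SE 0.534) and the sodium channel gene Scn7a at 1.25 (SE 0.494) in the authors' deposited table. Myelin genes had a median of 0.66 (14 of 18 positive, limma cameraPR, adjusted p = 0.00164) and satellite glia markers one of 0.80 (9 of 11 positive, adjusted p = 0.015). The median mouse level of myelin genes was 1.55% of the rat level. Rat reads assigned to mouse transcripts could therefore contribute to the myelin list, which was not weighed separately. The satellite glia call was lost with a preset correlation of 0.05 (adjusted p = 0.0556) and without Cdh19 (adjusted p = 0.176). Cholesterol synthesis genes had the opposite sign, negative in 24 of 25 members with a median of -0.37 (limma cameraPR, adjusted p = 0.000156), although none passed singly. Pan-neuronal and sensory neuron lists had medians of 0.01 and 0.01, with adjusted p-values of 0.811 and 0.818. The other 21 of the 26 lists tested had adjusted p-values between 0.0794 and 0.882, and macrophage markers had no tested member. Of these, glycolysis and lactate (negative, 0.0794) passed on ranks (0.0134). Pyruvate entry and the TCA cycle, positive in 23 of 26 members (0.0794), passed on ranks (0.0157), without its largest member (0.024) and without the filter on low means (0.000197).

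**Figure D3:**
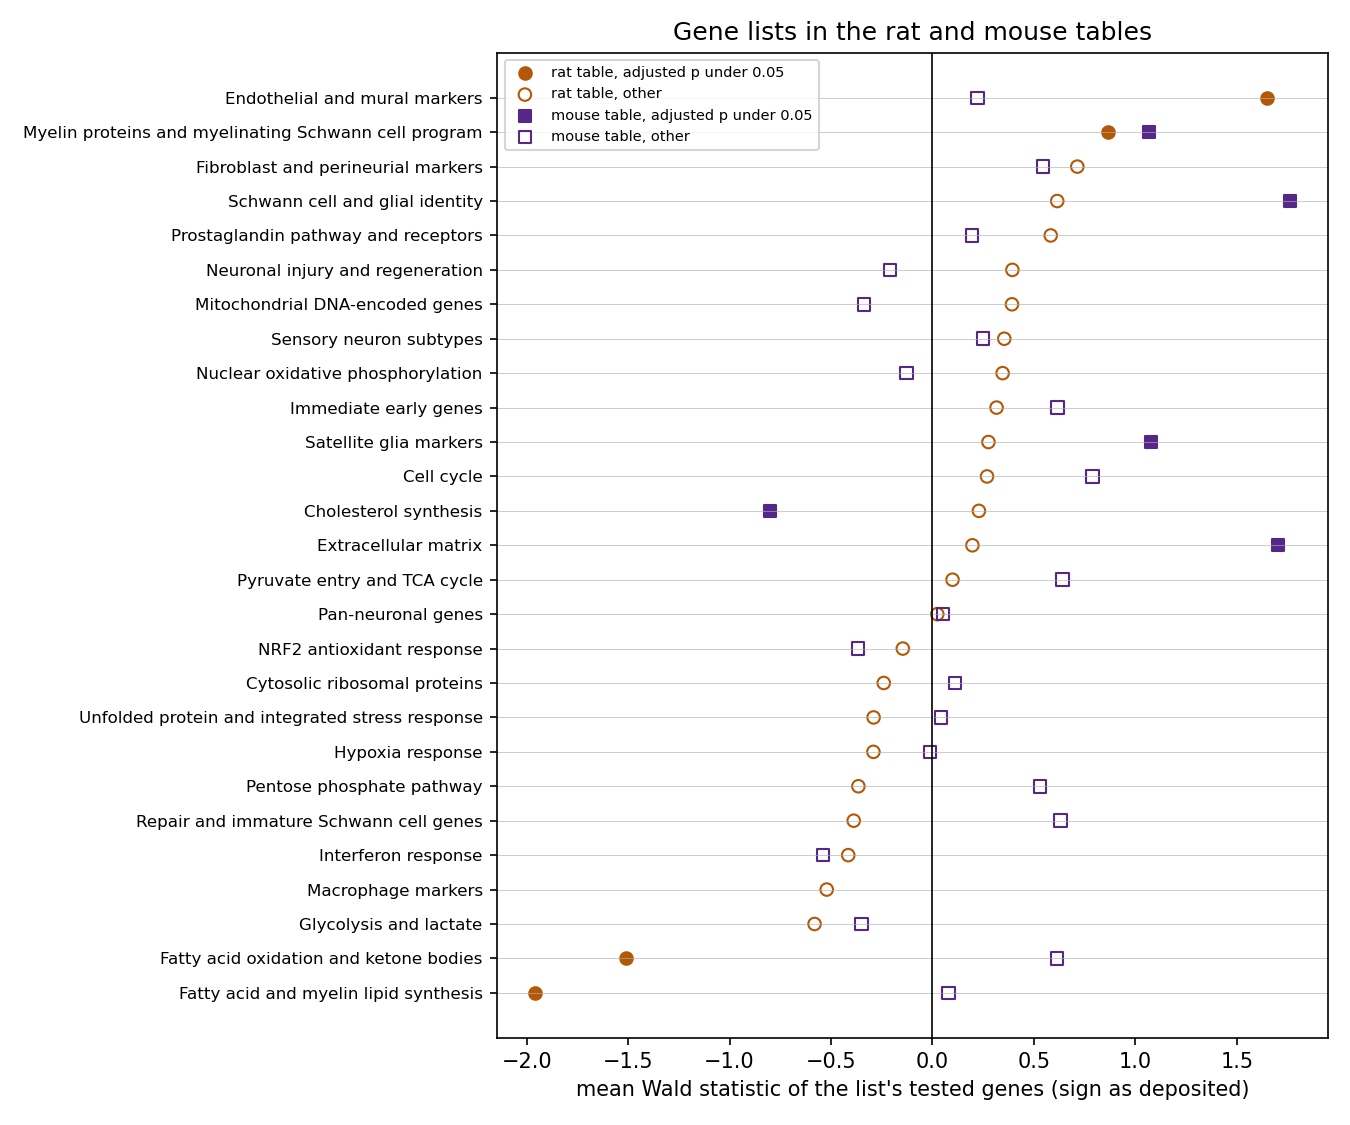
Mean Wald statistic of each gene list's tested members (horizontal axis, sign as deposited) in the rat table (circles) and the mouse table (squares). Filled symbols mark lists with an adjusted p under 0.05 by limma cameraPR, 4 in the rat table and 5 in the mouse table.

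The rat and mouse tables were then compared directly over 9221 symbols tested in both, with the signs as deposited. No single symbol differed after adjustment (0 at an adjusted p of 0.05, normal test on the deposited standard errors). Fold sizes of the 2 tables are not on the same scale, so equal responses need not give equal values in this test. With the rat sign turned, as would apply if the tables had opposite numerators, 11 symbols differed. With the signs as deposited, the smallest adjusted p of the difference, 0.112, was shared by Egfl8 and Postn. Egfl8 had a log2 fold change of -0.19 (SE 0.161) for rat and 2.35 (SE 0.56) for mouse in the authors' deposited tables. For Postn, the authors' deposited tables gave 0.05 (SE 0.152) and 2.25 (SE 0.498). Cdh19, Nr4a1 and Abca8a were the next genes lower for rat than for mouse, with differences of -2.16, -2.36 and -2.23 and adjusted p-values of 0.116 to 0.184. Tm4sf1, Spp1, Zpld1, Gphn and Tnfaip6 led in the other direction, with differences from 1.65 to 1.89 and adjusted p-values of 0.334 or more. This order depends on a shared numerator. Tm4sf1 was at 0.75 (SE 0.159) for rat and -1.14 (SE 0.495) for mouse in the authors' deposited tables, values of equal sign once the rat sign is turned. Across the symbols tested in both, which are not independent replicates, the Spearman correlation of the log2 fold changes was 0.077.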

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

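The tests for glial and matrix genes that concern rat reads and the share of positive members were chosen after the lists' values were seen. The test on genes outside the lists was fixed before its result was seen. Whether a list's difference was unequal between the rat and mouse tables was tested on the difference itself over 26 lists, and 8 lists differed (limma cameraPR on the difference statistics). Both tables came from the same libraries, their fold changes are on unequal scales, and it is not stated whether they share a numerator, so the differences were also computed with the rat sign turned, a test chosen after the results were seen.

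Extracellular matrix genes were higher in sign in the mouse table in 25 of 27 members, with medians of 0.94 against 0.04 (adjusted p = 5.84e-10). Schwann cell and glial identity genes were higher in 12 of 14, with medians of 1.01 against 0.07 (adjusted p = 8.53e-06). Cholesterol synthesis genes were lower in the mouse table in 24 of 25 members, with medians of -0.37 against 0.04 (adjusted p = 4.48e-06). Fatty acid oxidation and ketone body genes were higher in the mouse table in 22 of 26 members, with medians of 0.40 against -0.06 (adjusted p = 0.00158). These 4 lists passed on ranks, with a preset correlation of 0.05 and without their largest member as well. Myelin genes, satellite glia markers and nuclear oxidative phosphorylation each had an adjusted p of 0.0362, and NRF2 antioxidant genes had 0.0416. Each of these last 4 was lost in 2 or 3 of those 3 alternatives. With the rat sign turned, 6 of the 8 lists passed in the same direction, extracellular matrix with an adjusted p of 1.16e-11, cholesterol synthesis with 5.83e-05 and glial identity with 8.32e-09. Fatty acid oxidation and ketone bodies (adjusted p = 0.389) and nuclear oxidative phosphorylation (0.159) were lost, so these 2 differences depend on a shared numerator. Glycolysis and lactate (0.00329) and fatty acid and myelin lipid synthesis (0.0159), which had not passed as deposited, passed with the rat sign turned. Among lists that had not passed, glycolysis and lactate (0.0365) and the genes of mitochondrial DNA (0.00451) also passed on ranks with the signs as deposited.

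The positive sign of glial and matrix genes in the mouse table was weighed against 3 explanations. Rat reads assigned to mouse transcripts would carry the rat fold change with them, and the difference of the glial list from its rat values (adjusted p = 8.53e-06, and 8.32e-09 with the rat sign turned) argues against that. A share of such reads that was unequal between the groups would lift other genes with mouse levels below 2% of the rat level as much. Their median was 0.38 over 2515 genes (quartiles 0.12 and 0.65), under the 1.01 of the glial list but above the 0.08 of genes with higher mouse levels. These genes were not matched to the glial list on mouse mean, mouse means are approximate, and moderated folds of weakly expressed genes understate differences. The gap therefore cannot decide whether an unequal share was the whole cause or a part, and that explanation stays open. A different amount of mouse glia and fibroblasts between the groups cannot be told apart from a change of expression in such cells. Of 49 members of the glial, fibroblast and matrix lists 89.8% were positive, against 61.5% of all tested mouse symbols. The share of the lists was seen beforehand and would be the same under either explanation, so it supports neither. It also pools unequal lists: the fibroblast and perineurial markers had 6 of 8 members positive, a median of 0.13 and an adjusted p of 0.415, near the median of 0.12 of all tested mouse genes. A different amount of fibroblasts therefore has no support from its own markers, which are too few to exclude it, and both explanations stay open for the glial and matrix genes.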

How the results depend on the processing

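Alternatives without a filter on low means, with a mean of at least 5 CPM, with a 1.5-fold minimum, without genes at a near equal level in both tables and without mitochondrial genes were fixed before the data were examined, and the others were chosen after seeing the data. No paired analysis was possible because the deposited tables hold no values of single libraries. For that reason other normalizations, DESeq2 and limma-voom fits, the replicate block, leaving out replicates, rounding, pseudocounts, an estimated correlation, fry, other prior counts and other splits of the 6 samples were not run. The rat count of 258 genes was 128 with the 1.5-fold minimum and between 208 and 314 otherwise, and 224 when called genes whose gene numbers lay within 2 of each other counted once. The mouse count of 0 became 6 without genes at a near equal level in both tables (1 negative, 5 positive), 14 at an adjusted p under 0.1, and 2 after centring on the median (2 negative). The first of these tests fewer genes, and the cause of the last was not tested. The glycolysis list of the rat table passed without the filter (adjusted p = 0.0115, and 0.0551 to 0.266 in the other alternatives). The rat myelin list was lost with a preset correlation of 0.05 (adjusted p = 0.0758, and 0.000319 to 0.0488 in the others). The rat fibroblast list passed without the filter as well (adjusted p = 0.0177, and 0.0654 to 0.414 in the others). For these 3 lists the cause was not tested. The number of lists past 0.05 was 4 in the rat table and 2 on ranks, and 5 in the mouse table, 8 on ranks and 12 without the filter. The lists gained on ranks were glycolysis and lactate (0.0134), pyruvate entry and the TCA cycle (0.0157) and mitochondrial DNA (0.0157). Those gained without the filter were the TCA cycle (0.000197), pentose phosphate (0.0469), fatty acid oxidation (0.00165), repair genes (0.00165), interferon (0.0405), cell cycle (9.91e-06) and immediate early genes (0.0233). Interferon also passed with at least 5 CPM (0.0197), and fatty acid oxidation without its largest member (0.0328). With the rat sign turned, the count of symbols that differ between the tables was 11 in place of 0, and the cause was not tested. Of 515 alternative values 470 kept their side of the threshold or stayed within 1.5 times. The difference between the tables in fatty acid and myelin lipid synthesis, which had not passed, changed sign and passed with the rat sign turned (adjusted p = 0.0159). The rat share was 96.49% without mitochondrial genes, and it can be too high because some restored mouse means came out too low.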

Other observations

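Tests below on overlapping genes, on mouse cells responding like rat cells and on target gene lists were fixed before their results were seen. Those on rat reads in the mouse table and on chance neighbours were chosen after the values were seen.

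Further genes called in the rat table, named after their values were seen, included the following. In the authors' deposited table the phospholipid acyltransferase gene Lpcat3 was at -0.62 (SE 0.0899) and the phagocytosis receptor gene Mertk at -0.73 (SE 0.127). With the opposite sign, the authors' deposited table had Txnip, a glucose-responsive inhibitor of thioredoxin, at 0.62 (SE 0.158) and the fatty acid binding protein gene Fabp3 at 0.57 (SE 0.161). The matrix genes Thbs1 and Mmp14 were at 0.72 (SE 0.161) and 0.37 (SE 0.0735) in the authors' deposited table, within a matrix list that did not pass (adjusted p = 0.525).

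Several of the negative lipid genes are textbook targets of the sterol receptors LXR, and others of the fatty acid receptors PPAR. The hypothesis that these target lists moved together was tested on members whose values had not been seen. The 10 LXR targets that prompted it had a median log2 fold change of -0.89, whereas the 9 other targets had a median of -0.04, with 5 negative, 4 positive and 0 called (limma cameraPR, p = 0.48; permutation of genes, p = 0.43). Mylip and Pltp among them were at 0.01 (SE 0.138) and 0.01 (SE 0.136) in the authors' deposited table. For PPAR the 5 prompting genes had a median of -1.14 and the 14 others -0.05 (limma cameraPR, p = 0.73; permutation of genes, p = 0.69), with Fabp4 called negative and Fabp3 and Txnip called positive. The permutation of genes, with 10000 draws, was added after the limma results were seen. The prompting genes were all called and negative, 10 of 10 for LXR and 5 of 5 for PPAR. The unseen members were those left once these had been set aside, so they hold fewer responders by selection. Their test therefore cannot decide whether either list moved as a whole, and a response of part of the targets stays open.

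Called genes of the rat table often stood on neighbouring rows. Of 258 called genes 52 had a called gene on the next or previous row, against at most 16 in 1000 shuffles of the calls, which argues against chance, and in all 30 such pairs the signs were equal. In the mouse table, whose rows follow genome order, the correlation of Wald statistics between neighbouring rows was 0.646 for 1203 overlapping pairs and 0.208 for 2806 others, a difference of 0.437 (95% bootstrap interval 0.375 to 0.498). Reads counted for overlapping genes may therefore explain part of the neighbouring calls, such as Prkca with Trnaa-agc and Clcnkb with Hspb7, but positions in the rat genome were not used here. Shared regulation of neighbours was not tested.

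Genes called in the rat table had weakly related values in the mouse table. Over the 141 called genes tested in both, the Spearman correlation of the log2 fold changes was 0.222, and 77 had the same sign. Over all 9221 symbols tested in both it was 0.077, and 4800 had the same sign. Over 89 called genes with a mouse mean below 5% of the rat mean, the Spearman correlation of the log2 fold changes was 0.298 (permutation p = 0.0047), although only 44 of 89 had the same sign. Rat reads assigned to mouse transcripts would give a positive correlation if the tables share a numerator, which is not stated. With opposite numerators the correlation would be negative and would count against such reads, so that explanation stays open. Over 120 called genes with a mouse level of at least 20% of the rat level, each relative to the sum of its table, it was 0.286 (permutation p = 0.0015). The sign of this correlation has the same limit. The same response in mouse cells cannot be told apart from such reads there, because the mouse mean of these genes was at a median of 3.9% of the rat mean, and only 13 called genes had a mouse mean of 20% or more. The sets of 89 and 120 genes came from the same 141 and overlap, so their correlations are not separate results. The permutation takes genes as independent, although neighbouring called genes may share reads, so both p-values can be too small. Mouse means are approximate, so some genes may stand on the wrong side of the 5% and 20% limits.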
